A study of Drosophila melanogaster with 12 samples.

How the data were processed

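RNA-seq libraries of Drosophila S2 cells were compared after 4 days of treatment with double-stranded RNA (dsRNA) against GFP, Sin3A, Sam-S, or Sin3A and Sam-S together. S2 is a cultured line derived from late embryos, with features of the macrophage-like blood cells called hemocytes. Each of the 4 groups had 3 samples, which the series design text calls biological replicates. The labels say that the replicates of a group were combined, and the 3 tables analysed here hold 1 pooled value per gene and group.

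Reads were converted with bcl2fastq and compared with Cuffdiff on genome build dm3, per the submitters' processing notes, which name no versions. The aligner, gene annotation, strand setting and filters are not given in the sources used here. Per the file headers, each table gives for every gene row an FPKM (fragments scaled to transcript length and to all mapped fragments) in the GFP control and an FPKM in the knockdown. Per the file headers, the authors' deposited tables also give a test statistic, a score with no fixed range, and the p-value and q-value of the authors' comparison. The values of a group have no SD, because they are pooled. Read counts and library depths are not analysed here. Ratios of low FPKM values showed no whole-read steps from which relative depth could be read: among 1718 untested rows of single genes, at most 6 shared 1 ratio to 0.001. Depth is therefore unknown, and no counting interval is given.

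The SIN3 table has 14542 rows and the SAM-S and double tables have 14540 each. Rows were joined by locus and gene symbols (14445 rows), or by locus and at least 1 shared symbol (72 rows). In the SAM-S and double tables, 5 gene symbols had turned into dates, and they were restored from the SIN3 table at the same locus. GFP values of the tables differed by a common factor: the SAM-S and double tables stood at a median ratio of 1.006 with no row off by more than 1%, while 117 of 11833 rows of the SIN3 table departed from the SAM-S table's ratio by more than 1%. Rows that merge several symbols (448 in the SIN3 table, 516 in each other table) are named with all of their symbols. Reads of overlapping genes, of antisense partners and of near-identical copies such as the Hsp70 genes cannot be told apart in such tables, so their values are uncertain. Coordinates are those of the files on dm3. Their starts count from 0, since end minus start equals the gene length of the current annotation for 4138 of 10821 single-gene rows and falls short by 1 for 71, so 1 was added to each start.

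Log2 fold changes were computed from the deposited FPKM without a pseudocount and differed from the deposited log2 column by at most 1.4e-05. A gene was called when the authors tested it and its deposited q was under 0.05. The deposited q of the SAM-S and double tables equal a Benjamini-Hochberg adjustment over the tested genes of each table, whereas those of the SIN3 table differ from it by up to 0.0427. The smallest deposited p is 5e-05, which sets the smallest q at 0.00172, 0.0306 and 0.00157 in the SIN3, SAM-S and double tables. Because the labels say that replicates were combined, it cannot be told whether these p-values measure the spread between the samples of a group. The same holds for standard errors taken from the statistic.

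A test of the difference between tables had been planned on the condition that the statistic behaved as a normal statistic for the deposited p. It did not: the normal quantile of p was a median of 1.74 times the statistic in the SAM-S table, and 1.73 to 1.74 times in the others. Differences between tables are therefore given as values. An approximate test was added after seeing the data. It took the log2 fold change over the statistic, divided by the root of 3, as a standard error, and used the 7594 of 7870 rows whose rescaled statistic tracked p in every table. It treats the tables as independent although they share the control, so its standard errors are too large; an alternative added after seeing the data counts the control once. The median standard error obtained this way was 0.238, 0.222 and 0.236 in the SIN3, SAM-S and double tables.

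The 22 gene lists and the rule for named genes were fixed before the data were examined. The rule took Sin3A and Sam-S in every table, and per table the 10 called genes that rose most and the 10 that fell most with an FPKM of at least 5 in the higher and 0.5 in the lower condition. It also took up to 2 called genes per direction and list, 5 genes per direction called alike in all tables, and 5 per direction with the largest departure of the double from the sum of the single knockdowns. For each list, the median log2 fold change was set against 10000 random lists of the same size matched on deciles of mean FPKM, which describes these libraries and tests nothing across samples. The comparisons share their GFP libraries, so unchanged groups were simulated 100 times against 1 control with the standard errors above. Alternatives were a q of 0.01, a minimum fold of 1.5, a minimum mean FPKM of 1, p adjusted again, p from the statistic, centring, a pseudocount of 1, and leaving out merged rows. Scripts in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated tables of 7870 genes, the rescaled test called 63% of genes changed by 1 log2 unit and 91% of those changed by 2 in the SIN3 comparison, and 67% and 92% in the double comparison. For a departure of 2 log2 units it called 73.5%.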

Results

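Gene expression was measured by RNA-seq in Drosophila S2 cells that had taken up dsRNA for 4 days. The dsRNA targeted GFP as a control, Sin3A, Sam-S, or both genes. Sin3A encodes the scaffold of a histone deacetylase complex, and Sam-S encodes S-adenosylmethionine synthetase, which makes the methyl donor of histone and other methylation. Each group had 3 samples, pooled by the authors into 1 FPKM per gene and group, so no value carries a spread between replicates. The authors tested 8123 genes in the SIN3 table, 7957 in the SAM-S table and 8158 in the double knockdown table, each against the same GFP control. The median tested gene stood at 24.1 FPKM in the control of the SIN3 table.

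The targeted genes check the labels. Sam-S (chromosome 2L, 106903 to 114432) fell from 242 to 62.0 FPKM after SAM-S knockdown, a log2 fold change of -1.96, with q = 0.0306 in the authors' deposited table. In the double knockdown it fell from 243 to 91.2 FPKM (-1.41), with q = 0.00157 in the authors' deposited table. Sin3A (chromosome 2R, 8459617 to 8480397) stood at 67.9 FPKM in the control and 61.7 FPKM in the samples labelled SIN3 knockdown, a log2 fold change of -0.14 with q = 0.931 in the authors' deposited table. In the samples labelled double knockdown it stood at 64.7 against 68.5 FPKM (-0.08), with q = 0.93 in the authors' deposited table. After SAM-S knockdown the corresponding values were 71.2 and 68.1 FPKM. The Sin3A mRNA level thus does not bear out the label of the samples labelled SIN3 knockdown or, for Sin3A, of the samples labelled double knockdown, and every direction given for them rests on the label.

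**Figure D1:**
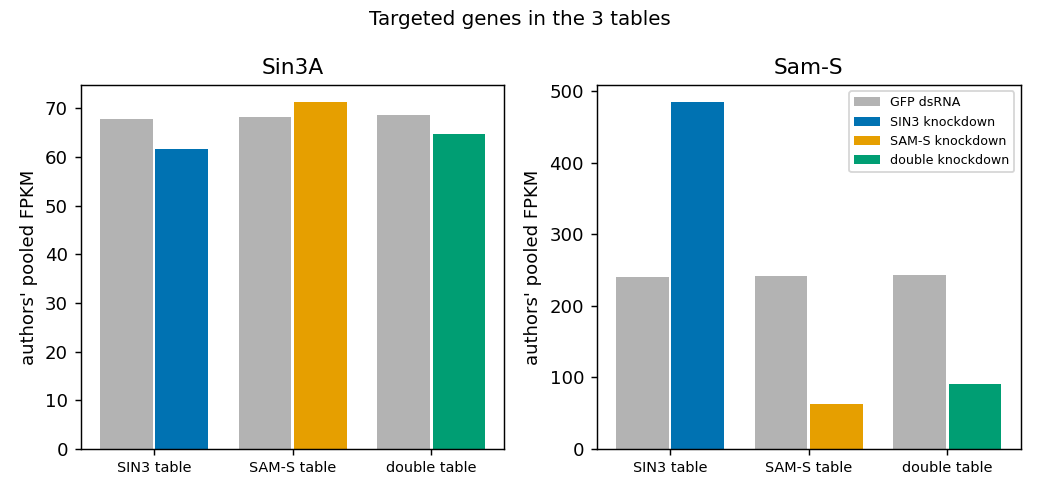
Authors' pooled FPKM of Sin3A (left) and Sam-S (right) in each of the 3 tables, with the GFP control in grey and the knockdown in colour; pooled values carry no error bars. Sin3A stays between 61.7 and 71.2 FPKM in every column, while Sam-S is lower after SAM-S and double knockdown and higher, at 484 FPKM, in the samples labelled SIN3 knockdown.

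The first comparison asked which genes depend on SIN3. In the samples labelled SIN3 knockdown, 271 genes rose and 353 fell, together 7.68% of those tested, and 248 of the called genes changed at least 2-fold. Sam-S itself rose from 240 to 484 FPKM, a log2 fold change of 1.01. Falls included 8 of 18 heat shock and chaperone genes, 9 of 19 hemocyte markers and 7 of 34 DNA replication genes, and the genes that rose most included the esterase gene alpha-Est3 (chromosome 3R, 3364694 to 3367349), from 4.14 to 19.5 FPKM (2.24). CG15784 (chromosome X, 5324713 to 5326494) rose from 66.9 to 212 FPKM (1.67) and Aprt, which salvages adenine, from 25.4 to 63.6 FPKM (1.32). CG1969, CG8301, CG7328, CG1635, CG3608, CG4942 and Dgp-1 rose by 1.33 to 1.59 on the log2 scale. The largest falls were those of CG13386 (chromosome 2L, 8399044 to 8399972), from 8.61 to 1.02 FPKM (-3.07), and CG33307, from 103 to 14.8 FPKM (-2.80). CG4250 and CG4829 each had a log2 fold change of -2.74, the tetraspanin gene Tsp42Eg -2.62, CG14527 -2.62, CG42566 -2.61 and the glutathione transferase gene GstD7 -2.21. Of these rises and falls, those of alpha-Est3, CG15784, Aprt, CG1969, CG8301, CG1635, CG3608, Dgp-1, CG13386, CG4250, CG4829, Tsp42Eg, GstD7 and Sam-S had q = 0.00172, the smallest in the authors' deposited table.

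Methionine metabolism moved in both directions among the 19 tested members of its list, of which 2 rose, 2 fell and 15 were not called. Ahcy13, which hydrolyses S-adenosylhomocysteine, rose from 154 to 223 FPKM (0.53) and the homocysteine methyltransferase gene CG10623 from 11.3 to 24.3 FPKM (1.10). The thymidylate synthase gene Ts fell from 80.3 to 36.2 FPKM (-1.15) and Cbs, which makes cystathionine, from 30.0 to 16.4 FPKM (-0.87). The same numbers rose and fell when p was adjusted over the list alone. Among 14 glycolytic genes 3 rose, with ImpL3, encoding lactate dehydrogenase, at 0.81 and Pgm at 0.81, and 3 were also called when adjusted over the list alone. Of 23 genes of the amino acid and integrated stress responses, the translation inhibitor gene Thor (0.84) and the amino acid transporter gene JhI-21 (0.53) rose, Sesn (chromosome 2R, 19601425 to 19620706), a regulator of TORC1, fell (-1.75), and 20 were not called. Adjusted over the list alone, 2 rose and 1 fell. Among 27 lipid genes, the ethanolamine kinase gene eas (-1.58) and the acyl-CoA ligase gene bgm (-1.23, or -0.80 with 1 added to each FPKM) fell, the same 2 as a count when adjusted over the list alone, although 19 of the 27 members had positive values and the list median was 0.22.

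In the same samples, 8 of 18 tested heat shock and chaperone genes fell (9 adjusted over the list alone), with a list median of -0.72, below all 10000 matched random lists. Hsp23 (chromosome 3L, 9374982 to 9375865), a small heat shock protein gene, fell from 427 to 167 FPKM (-1.36) and Hsp70Bc from 22.8 to 8.92 FPKM (-1.35). The constitutive chaperone gene Hsc70-4 had a log2 fold change of 0.11 and was not called. Of 19 hemocyte markers 9 fell and none rose (11 fell adjusted over the list alone), with Pxn, encoding the matrix enzyme peroxidasin, at 151 and 50.9 FPKM (-1.57) and the neuropeptide-like gene Nplp2 at 24890 and 10670 FPKM (-1.22). Of 34 DNA replication and cell cycle genes 7 fell (14 adjusted over the list alone), among them the helicase subunit gene Mcm7 (-0.68) and the mitotic kinase gene polo (-0.63), and 30 of the 34 had negative values. Both of these lists had medians below all 10000 random lists, at -0.49 and -0.39. Of 75 mitochondrial ribosomal protein genes 2 rose (2 adjusted over the list alone), mRpL40 at 1.04 and mRpL19 at 0.82, and the list median of 0.24 lay above all random lists. Cytoplasmic ribosomal protein genes had a median of -0.16, below all random lists, and 80 of 86 were negative, but the only call (1 adjusted over the list alone) was RpL28, which was higher at 1.21. RpL28 shares its row with snoRNA genes in the other tables.

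The remaining lists gave few calls in this comparison. In the glutathione and detoxification list of 28 genes, Keap1 rose (0.71) and GstD3 (-1.15) and Cyp9f2 (-0.77) fell, again 1 and 2 when adjusted over the list alone. Of 19 TCA cycle genes only CG6439 was called, at 0.55, and of 32 immune genes only AttB, at 1.15, which was lost when p was adjusted over the list alone. The ecdysone list of 15 had Eip74EF lower, at 1.92 against 3.85 FPKM, and the merged Eip71CD row higher (0.63). No member was called among 10 SIN3 complex genes, 27 histone methyltransferase and demethylase genes, 12 RNA interference genes, 34 respiratory chain genes, 29 proteasome genes, 5 neuron, 5 muscle and 11 germline markers, while over the whole table Cuffdiff gave 1466 genes an unadjusted p under 0.05. The histone deacetylase gene Rpd3, a SIN3 partner, stood at 72.9 against 102 FPKM (-0.49) with q = 0.0653 in the authors' deposited table. Among markers of other tissues, the germline list had a median of -0.53 with 17 of 10000 random lists as low, and 1 of 3 fat body and gut markers, Rfabg, fell (-0.85, or -0.52 with 1 added to each FPKM). The number of calls depended on how p was taken: with a normal p from the deposited statistic after centring, 7 genes rose and 29 fell, which moved the share of rises from 43.4% to 19.4%.

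The second comparison asked which genes depend on SAM-S. After SAM-S knockdown 7 genes rose and 6 fell of 7957 tested, and 223 genes had an unadjusted p under 0.05 in Cuffdiff's test. Apart from Sam-S, the genes that fell were Sesn, from 26.3 to 12.9 FPKM (-1.02), the mitochondrial cytochrome P450 gene Cyp12a5, from 45.4 to 24.3 FPKM (-0.90), Hsp27, from 448 to 268 FPKM (-0.74), Hsp23, from 429 to 257 FPKM (-0.74), and the merged row of mir-4940 and nwk. That row, named after its values were seen, stood at 21.3 FPKM in the control and 0.0639 FPKM in the knockdown. It was as low in the double knockdown, at 0.0623 FPKM with q = 0.00157 in the authors' deposited table, and at 0.0446 FPKM but not called in the samples labelled SIN3 knockdown, with q = 0.266 in the authors' deposited table. Its statistic is small for its p: the approximate 95% interval of its log2 fold change after SAM-S knockdown runs from -25.9 to 9.2. Since the row was low in every group set against the GFP samples, a high value in those samples cannot be told apart from a fall. The genes that rose included the merged row of Eip71CD, Z600 and gdl (chromosome 3L, 15502161 to 15506302), which rose 11.1-fold to 610 FPKM (3.47); Eip71CD encodes methionine sulfoxide reductase. The Notch target gene E(spl)mbeta-HLH rose from 7.71 to 25.6 FPKM (1.73) and the non-coding RNA gene CR43264 from 240 to 462 FPKM (0.95). The amino acid transporter gene path rose from 45.8 to 80.6 FPKM (0.82), Fib, encoding the rRNA methyltransferase fibrillarin, from 83.9 to 137 FPKM (0.70), and r, which starts pyrimidine synthesis, from 28.6 to 44.1 FPKM (0.63). The RpL28 row (chromosome 3L, 3219156 to 3222960), merged with 2 snoRNA genes, rose from 2149 to 8695 FPKM (2.02). All 13 calls had q = 0.0306, the smallest value in the authors' deposited table.

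Gene lists shifted little after SAM-S knockdown, and the median absolute log2 fold change over tested genes was 0.116, against 0.233 in the samples labelled SIN3 knockdown. Among 18 heat shock genes 2 fell (6 adjusted over the list alone), and the median of -0.35 was below all 10000 random lists. DNA replication genes had a median of -0.145, with 32 of 34 negative and none called over all genes or over the list alone. Respiratory chain genes had a median of 0.16 with 32 of 34 positive, and mitochondrial ribosomal protein genes a median of 0.12, both above all random lists with no member called either way. Hemocyte markers, of which 9 of 19 fell in the samples labelled SIN3 knockdown, had a median of 0.13 with 36 of 10000 random lists as high and no call. Immune genes had a median of -0.13 with 37 random lists as low. The methionine list had 18 tested members and no call, and its Ahcy13 value was 0.46 with q = 0.9999 in the authors' deposited table. Calls elsewhere were Sesn in the stress response list, the merged Eip71CD row in the ecdysone list and the RpL28 row among ribosomal protein genes, each also called when adjusted over the list alone. The other lists had no call, with medians from -0.17 for neuron markers to 0.06 for the proteasome.

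The third comparison combined both treatments. In the samples labelled double knockdown 284 genes rose and 501 fell, 9.62% of those tested, and of all lists the heat shock genes had the lowest median. Of 18 tested, 11 fell (11 adjusted over the list alone), with a median of -2.04, below all 10000 random lists. Hsp27 (chromosome 3L, 9377163 to 9378382) fell from 451 to 67.3 FPKM (-2.74), Hsp26 from 674 to 107 FPKM (-2.66), Hsp23 from 431 to 74.6 FPKM (-2.53), Hsp68 from 350 to 57.4 FPKM (-2.61) and Hsp70Bc from 23.0 to 2.69 FPKM (-3.09). The heat shock factor gene Hsf, at 0.12, and Hsc70-4, at 0.11, were not called. The merged row of CG31675 and CG9338 (-3.02), Tsp42Eg (-2.50) and Sesn (-2.50) were also among the largest falls. The largest rises were those of the merged Eip71CD row, from 55.3 to 848 FPKM (3.94), CG15784, from 67.6 to 259 FPKM (1.94), CG31950 (1.70), CR43264 (1.62) and alpha-Est3 (1.48). CG5377, CG34149, CG15766, CG1969 and CG15390 rose by 1.29 to 1.46 on the log2 scale. The smallest q in the authors' deposited table, 0.00157, was reached among others by Hsp27, Hsp26, Hsp23, Hsp68, Hsp70Bc, Sesn, CG15784 and the merged Eip71CD row.

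DNA replication and cell cycle genes fell in 15 of 34 cases (19 adjusted over the list alone), with Mcm7 at -1.07 and the ribonucleotide reductase gene RnrL at -0.90, and a median of -0.555 below all random lists. Mitochondrial ribosomal protein genes rose in 8 of 75 cases (10 adjusted over the list alone), with mRpL40 at 1.22 and mRpS18C at 1.08, and a median of 0.36 above all random lists. Respiratory chain genes rose in 4 of 34 cases (4 adjusted over the list alone), with the Rieske protein gene RFeSP at 0.92 and CG5703 at 0.63; 12 random lists had as high a median as 0.23. The proteasome list had a median of 0.22, with 46 random lists as high and no call. In the methionine list Ahcy13 (1.14) and CG10623 (0.76) rose and Ts fell (-1.10), again 2 and 1 adjusted over the list alone. Hemocyte markers fell in 6 of 19 cases (7 adjusted over the list alone), with Pxn at -1.40 and Hml, which was below 1 FPKM throughout, at -1.40 (-0.46 with 1 added to each FPKM), and a list median of -0.16. In the lipid list 4 of 27 fell (4 adjusted over the list alone), with eas at -1.59 and bgm at -1.22 (-0.80 with 1 added to each FPKM). In the glycolysis list of 14 genes Pfk rose (0.59) and Pgi fell (-0.61), both also called when adjusted over the list alone.

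The other lists of the double knockdown had few calls. Sap130 of the SIN3 complex rose (0.67), the TCA cycle gene CG11876 rose (0.78), AGO2 of the RNA interference list fell (-0.81), Dro rose (1.42) and Tep1 fell (-0.94) among 32 immune genes, and krimp fell (-0.60) among 12 germline markers. Keap1 rose (0.87) and GstD3 (-1.11) and Cyp9f2 (-1.02) fell in the detoxification list. In the ecdysone list Eip74EF (-1.02) and br (-0.65) fell beside the rise of the merged Eip71CD row. Among 86 ribosomal protein genes RpL8 (0.65) and the RpL28 row (0.63) rose and RpL15 (-0.72) and the row of CR42491 and RpL22 (-0.65) fell. Rfabg fell (-0.79, or -0.49 with 1 added to each FPKM) of the 2 fat body and gut markers tested. Histone methyltransferase, neuron and muscle lists had no call. Adjusted over the list alone, 5 germline markers fell, 2 muscle markers were higher and 1 lower, and 3 ecdysone genes were higher and 2 lower. Of the SIN3 complex genes, 1 was higher and 1 lower when adjusted in this way. With a normal p from the deposited statistic, 8 genes rose and 47 fell in the double knockdown, which moved the share of rises from 36.2% to 14.55%.

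**Figure D2:**
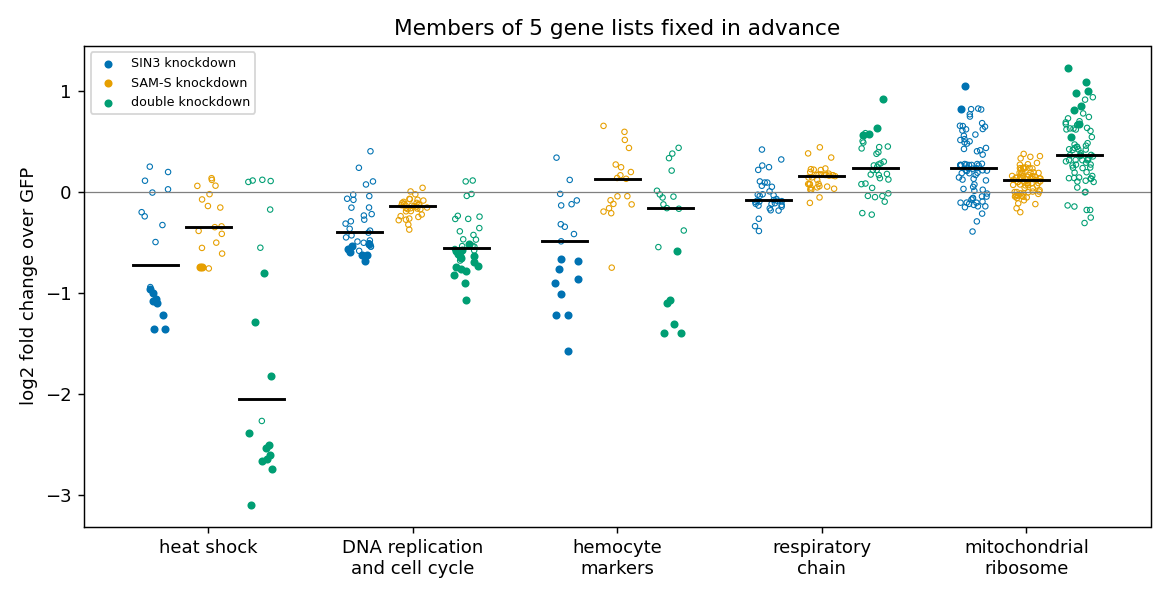
Log2 fold change over GFP of each tested member of 5 gene lists in the samples labelled SIN3 knockdown, SAM-S knockdown and double knockdown; filled points passed q under 0.05, open points did not, and black bars are medians. Heat shock medians step from -0.35 after SAM-S knockdown to -0.72 and -2.04 in the SIN3 and double samples, and mitochondrial ribosomal protein medians are 0.12, 0.24 and 0.36.

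The design also asks how the double knockdown relates to the single ones. Of the calls in the SIN3 table among genes tested in both, 141 of 270 rises and 282 of 353 falls were called in the same direction in the double table, where independent lists would share 9.44 and 21.9. All 6 falls and 4 of 7 rises of the SAM-S table were also called in the double table. The falls include Sam-S, the target in both groups, and the row of mir-4940 and nwk, which was low in every table. The single knockdowns shared 3 rises and 4 falls (0.238 and 0.265 for independent lists): CR43264, the merged Eip71CD row and the RpL28 row rose in every table, and Sesn, Cyp12a5, Hsp23 and Hsp27 fell in every table. Sam-S and E(spl)mbeta-HLH were called in opposite directions in the single knockdowns, the latter at -1.65 in the samples labelled SIN3 knockdown, and Sam-S was also the 1 gene called in opposite directions in the SIN3 and double tables. In the double table, 355 genes were called that were called in neither single table, 140 higher and 215 lower. Of these, 341 had the same sign in the SIN3 table and 345 in the SAM-S table, an agreement that the shared control favours, and absence of a call in a single table does not show a difference.

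Across 7376 genes with a mean of at least 1 FPKM and no small RNA in their row, log2 fold changes correlated at Pearson's r = 0.836 between the SIN3 and double tables, 0.551 between SAM-S and double, and 0.201 between SIN3 and SAM-S. Genes are not independent replicates. Unchanged groups simulated against a shared control gave 0.502, 0.497 and 0.475 and no shared calls in 100 draws. These correlations follow from giving the control as much of each variance as the knockdown. With every simulated gene unchanged, hardly any could be called. The lack of shared calls therefore does not tell how many observed shared calls come from the control. The observed covariances were 0.194, 0.0603 and 0.0208 and the simulated ones 0.164, 0.172 and 0.1505, so the standard errors implied by the statistic exceed the scatter of most genes in the SAM-S table, and the shared effect cannot be estimated from them. The GFP samples could not be split, so part of each overlap may come from the shared control.

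On the log2 scale the slope of the double knockdown on the sum of the single knockdowns was 0.716 over 7870 rows (95% bootstrap interval over genes, 0.672 to 0.759). The interval resamples genes, so it holds no spread between samples, and the slope without small RNA rows, 0.782, lay above it. Over the 7376 genes above, the slope was 0.82. Unchanged groups simulated against a shared control gave a mean slope of 0.358 over 100 draws (0.18 to 0.56). A positive slope alone therefore does not show that effects add up. Since noise alone gave slopes under 1, a slope under 1 does not show that effects fall short of the sum. Heat shock genes lay below the sum, with a median departure of -0.61 over 18 members, below all 10000 random lists. Among single rows, the departures were -2.60 for the RpL28 row, -1.55 for Hsp70Ba, -1.12 for Hsp70Bb, -1.05 for Hsp68 and -1.02 for Hsp26. Departures upward were 1.83 for CG13386, 1.20 for CG9336, 1.07 for GstD7, 0.88 for CG11703 and 0.75 for the gene ec. Each of these genes fell in the samples labelled SIN3 knockdown, to between 1.02 FPKM for CG13386 and 2.205 FPKM for GstD7. Their ratios thus rest on low values. In the approximate test over 7594 rows the RpL28 row was the 1 departure with Benjamini-Hochberg adjusted p under 0.05, and each other departure named here had an adjusted p of 1. The row of snoRNA:Me18S-U1356a, named after its values were seen, departed by -2.31 but was left out of that test because its statistic does not track its p. Of the other lists, 4 had median departures above and 1 below the central 95% of random lists: the respiratory chain at 0.14 and the proteasome at 0.13, both above all random lists, the ecdysone list at 0.17 and hemocyte markers at 0.12, with 19 and 9 of 10000 as high, and the lipid list at -0.07, with 114 as low. A departure still holds the pooled control value, so a joint shift of a list in the control moves its median departure. Random lists do not allow for such a shift. In the same test, 10 rows differed between the double and the SIN3 samples with Benjamini-Hochberg adjusted p under 0.05, 7 of them heat shock rows, and 74 differed between the double and the SAM-S samples. Over all 7870 rows the counts were 13 and 77, and without rescaling of the standard error 4, none of them a heat shock row, and 6. These tests combine the standard errors as if the tables were independent, which counts the shared control more than once and makes the tests cautious. With the control counted once, and taken to give as much of each variance as the knockdown, 42 and 479 of the 7594 rows differed and the RpL28 row was again the 1 departure.

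**Figure D3:**
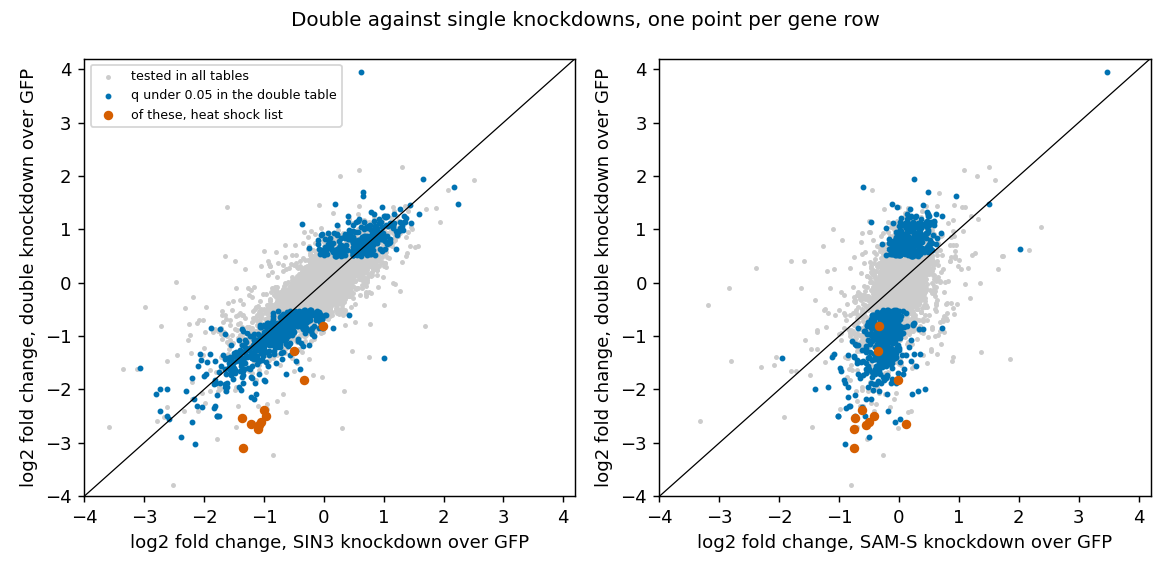
Log2 fold change over GFP in the double knockdown against that in the samples labelled SIN3 knockdown (left) and SAM-S knockdown (right), one point per gene row tested in all tables, with the line of equality and without rows beyond the axes; blue points passed q under 0.05 in the double table and orange points are those of them on the heat shock list. The 11 orange points lie below the line in both panels, with Hsp27 at -2.74 in the double and at -1.10 and -0.74 in the single knockdowns.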

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

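The tests on Sin3A, on heat shock genes and on the departure from the sum were chosen after their results had been seen. The heat shock tests cover every tested member of the list; a first form, on the called members alone, required each member to lie below 0, which 16 of the 18 members do for the double against the SIN3 samples. The test on Hsp70 copies took its present form, a count of calls, after 2 forms on medians, whose values are given with it.

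The row of RpL28 and 2 snoRNA genes stood out because its double knockdown departed from the sum of the single knockdowns by -2.60 on the log2 scale in the approximate test. It rose by 2.02 after SAM-S knockdown and by 1.21 in the samples labelled SIN3 knockdown, and by 0.63 in the double. The row merges a protein gene with short RNAs, and the tables do not separate their reads.

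The Sin3A mRNA level in the samples labelled SIN3 knockdown was close to the control. The authors' test called 624 genes in that table, against 13 after SAM-S knockdown, so these samples differed from the control. With a normal p from the deposited statistic, 7 genes rose and 30 fell, against 7 and 4 after SAM-S knockdown. Such counts cannot tell an effect of the dsRNA from another difference between cultures. They therefore do not decide whether the cells were untreated under a wrong label. Among genes tested in both, the double samples shared 141 of 270 rises and 282 of 353 falls of the SIN3 samples. Log2 fold changes of these groups correlated at r = 0.836, against 0.201 between the SIN3 and SAM-S samples, which have the same control. These values argue against a difference confined to the samples labelled SIN3 knockdown. Another difference common to both groups, and a part from the shared control, stay open. Imprecision of the kind that the statistic measures is argued against by the approximate 95% interval of the Sin3A log2 fold change. Its lower end, -0.56, does not reach a fall of 2-fold. That interval uses the standard error rescaled after seeing the data, which may hold no spread between samples, so it cannot exclude such a fall. Reads from the added dsRNA that mapped to Sin3A may have hidden a fall; the log2 fold change of -1.96 for Sam-S after its own dsRNA does not decide this for Sin3A, since read positions are not analysed here. A loss of SIN3 protein without a matching loss of mRNA also stays open and was not tested.

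Of the 11 heat shock genes that fell in the double knockdown, all 11 had negative values in the samples labelled SIN3 knockdown and 10 after SAM-S knockdown, Hsp70Ba being the exception, and all comparisons share the GFP samples. High heat shock expression in the control as the whole cause is argued against by the double samples, which lay below the SIN3 samples by a median log2 difference of -1.25 over all 18 tested members (SD 0.69), with 0 of 10000 matched random lists as low. Reads shared between the Hsp70 copies, as the whole cause, are argued against by the 14 tested members that are not Hsp70 copies. Of these 14, 8 fell, against 6.18% of 7852 rows off the list (two-sided Fisher's exact test, p = 4.83e-07). That test takes genes as independent, although members of a list may move together, so its p measures no spread between samples. The 14 had a median of -1.05 with an SD of 1.19, and 0 of 10000 random lists were as low. The 8 alone, picked for their fall, had a median of -2.46. Values of the Hsp70 copies themselves may still hold shared reads. The falls in the single knockdowns were not told apart from a control effect. SIN3 lay below SAM-S in 14 of 18 members by a median of -0.35 with an SD of 0.42 and 7 of 10000 random lists as low. The shared control cancels in this difference, which therefore goes against a high control as the whole cause in the SIN3 samples. The median lay within the SD between members, however, and under the rule set after seeing the data this leaves the question undecided. The fall after SAM-S knockdown, a median of -0.35, can be set against no control other than the shared one. A joint effect of SIN3 and SAM-S loss on these genes is a candidate explanation, although the Sin3A mRNA level shows no such loss. A difference in handling of the double samples also stays open, and neither was tested.

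Genes on chromosomes 4 and X were lower in the samples labelled SIN3 knockdown: 13 of 76 tested genes on chromosome 4 fell and 0 rose, and 74 of 1353 fell and 18 rose on chromosome X, against falls of 3.84% and rises of 3.81% of 6647 genes on the large autosome arms (two-sided Fisher's exact test on falls, adjusted p = 5.4e-05 and 0.0352 over 21 tests). A control effect is argued against by the SAM-S comparison, where the medians were -0.096 and -0.016 for chromosomes 4 and X, against -0.29 and -0.153 in the SIN3 samples, although 0 of 10000 matched random lists had as low a median as chromosome 4 after SAM-S knockdown, so a control effect as part of its fall stays open. Expression level and transcript length are argued against by matched random lists, of which 0 of 10000 had medians as low for either chromosome and either match. In the double samples 97 of 1361 genes on chromosome X fell and 26 rose, with an adjusted p of 0.154 on falls and a median of -0.121. Fisher's test takes genes as independent, so its p-values here measure no spread between samples. GC content was not tested, and a difference in chromosome number between the cultures may also lower a whole chromosome, so the pattern stays a hypothesis on SIN3 and chromosome-wide expression.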

How the results depend on the processing

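No paired analysis was possible because the tables hold 1 pooled value per group; for the same reason no replicate could be left out and no other split of the samples was made. At a q of 0.01 the SIN3 samples had 138 rises and 189 falls, SAM-S 0 and 0, since the smallest q is 0.0306, and the double 126 and 261, with 0 genes shared by the single knockdowns and 193 called in the double alone. A normal p from the statistic gave 7 and 30 in SIN3, 7 and 4 in SAM-S and 8 and 47 in the double, 2 shared and 27 in the double alone. After centring, the values were 7 and 29, 7 and 4, 8 and 47, 2 and 27. The SIN3 and double counts fall because the statistic is smaller than the normal quantile of p. With the rescaled standard error and centring, chosen after seeing the data, SAM-S had 12 rises and 11 falls, and 11 genes were shared by the single knockdowns. The other alternatives (a fold of 1.5, a mean FPKM of 1, p adjusted again, merged or small RNA rows left out) left these counts within 1.5 times of the reported ones. The slope of the double on the sum was 0.762 with a pseudocount of 1, 0.791 for called genes and 0.782 without small RNA rows; the cause was not tested. The approximate test over all rows gave 13 and 77 differences from the SIN3 and SAM-S samples with rescaling, 4 and 6 without it, and 2 departures either way, and 0 departures without small RNA rows, which include the RpL28 row; with the shared control counted once, chosen after seeing the data, it gave 42 and 479 differences and 1 departure. No named gene, and no list median outside the central 95% of random lists, changed sign. A pseudocount of 1 moved 13 values of named genes and lists by more than the implied standard error. Of the list medians inside that range, a minimum mean FPKM of 1 turned that of fat body and gut markers in SIN3 from 0.395 to -0.85 and that of neuron markers in the double from 0.053 to -0.034. Depth is unknown, which limits any statement on genes of low FPKM.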

Other observations

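The gene lists below were drawn up after Fib and r had been seen to rise, and both are left out of them.

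Nucleolar and ribosome biogenesis genes mostly had positive values after SAM-S knockdown, but none was called. Of 28 genes tested, 27 were positive with a median log2 fold change of 0.38, and 0 of 10000 matched random lists had as high a median. In the double knockdown 27 were again positive with a median of 0.39, and 4 were called, among them RpI135, mbm and CG12301, whereas in the samples labelled SIN3 knockdown the median was 0.01. Adjusted over the list alone, 3 members were called after SAM-S knockdown, and the random lists test nothing across samples. A joint rise of nucleolar genes after SAM-S loss is a hypothesis from these libraries, and a shared control cannot be excluded as part of it, although the SIN3 samples, set against the same control, did not show it.

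Aminoacyl-tRNA synthetase genes had positive values in 20 of 21 cases in the samples labelled SIN3 knockdown, with a median of 0.28 and 4 called, Aats-ala-m, Aats-cys, Aats-phe and Aats-tyr. Their median was 0.12 after SAM-S knockdown, with no call, and 0.36 in the double, where Aats-cys and Aats-tyr were called. Adjusted over the list alone, 5 synthetase genes rose in the SIN3 samples, 0 after SAM-S knockdown and 8 in the double. Of 10000 random lists, 4, 1 and 2 had as high a median in these comparisons. Purine and pyrimidine synthesis genes gave mixed calls: of 18 tested in the SIN3 samples, 2 rose and 2 fell, and in the double 3 rose and 1 fell. After SAM-S knockdown none of the 18 was called, and the median was 0.06 with 597 of 10000 random lists as high. The list median was 0.147 in the SIN3 samples and 0.24 in the double, with 636 and 172 random lists as high.

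On chromosome 4, yellow-h fell from 52.2 to 14.6 FPKM in the samples labelled SIN3 knockdown and from 53.2 to 10.4 FPKM in the double, where 16 of 76 tested genes fell and 0 rose. Genes on the heterochromatin scaffolds of dm3 fell in 11 of 47 cases in the SIN3 samples and in 8 of 46 in the double, with none higher, and their medians were -0.435 and -0.395. After SAM-S knockdown the heterochromatin median was -0.07 with no call.

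Rows that include a small RNA varied more than others. Their median absolute log2 fold change was 0.68 over 106 rows in the SIN3 samples, 0.44 over 140 after SAM-S knockdown and 0.475 over 159 in the double, against 0.23, 0.115 and 0.27 for other rows, and 0 of 10000 random lists matched on FPKM were as high in any table. Of these rows 0, 2 and 5 were called. They are part of the 127, 167 and 177 tested rows with a small RNA in the SIN3, SAM-S and double tables. With all such rows left out, falls went from 353 to 352 in the SIN3 samples. In the double, rises and falls went from 284 and 501 to 281 and 498. The sets also differ between tables, since RpL28 shares its row with snoRNA genes in all but the SIN3 table. FPKM is scaled to transcript length, so the match does not equal read counts, and counting noise in short RNAs cannot be told apart from real change.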
